A study of Mus musculus with 4 samples.

How the data were processed

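Lymphatic endothelial cells were sorted as CD45-negative, CD31-positive and GFP-positive cells from lungs of mice at postnatal day 0, with 3 to 5 mice pooled per group, per the labels' protocols. RNA was isolated with a PicoPure kit, amplified with a RiboAmp HS PLUS kit and made into libraries with a NEBNext Ultra II DNA kit, which does not mark strand, and sequenced on an Illumina HiSeq with reads of 79 bases, per the labels' protocols. Per the series' design text, cells from 3 replicates of a group were mixed before amplification, and the sources used here do not say whether the 2 libraries of a group come from separate sorts or amplifications. The deposited table holds raw read counts per gene for 24421 rows, one column per library, and a gene length in bases made by the authors, used here only to tell rows apart and for a correlation. STAR 2.7.2a, featureCounts 1.6.4, edgeR 3.28.1 and the build mm10 are named, without their roles, per the submitters' processing notes. The gene annotation and the strand setting of the counting are not given in the sources used here. Without strand, reads of a gene and of an overlapping or antisense gene cannot be told apart.

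Each column was matched to a library by its name, which is the library's title or that title without the cell type. Of the rows, 27 carry names that a spreadsheet had turned into dates, and 2 of those names stand on more than one row, which were kept as separate rows. No row was a total or an unassigned class. A count above 0 was seen for 16907 genes. A floor of 3 counts equals 0.182 and 0.459 CPM in the Jun-Ctrl libraries and 0.197 and 0.443 CPM in the Jun-cKO libraries. A group at 0 is set against 3 counts over the group, which covers counting error only, since amplified reads without molecular identifiers are not independent molecules.

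Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), after TMM normalization and filterByExpr, which left 12656 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. The comparison was Jun-cKO minus Jun-Ctrl with all 4 libraries and no block. Fold changes come from this fit, standard errors from the fold change divided by the root of its F statistic, 95% intervals from these and the moderated degrees of freedom, and CPM values are TMM-scaled. The biological coefficient of variation was 0.089. For a gene list with at least 5 tested members, camera of limma 3.58.1 was run with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and the directional fry test were run beside it.

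The 39 lists, their members and the rule for named genes were written before the data were examined. They cover lymphatic identity, valves, the AP-1 family and its targets, endothelial signalling and junctions, cell cycle, death, inflammation, metabolism, stress, matrix, ribosomes, and markers of the other cells a lung sort can hold. Named genes are Jun and all tested AP-1 family members, the 10 highest and 10 lowest fold changes among called genes with a mean of at least 50 counts and both libraries of one group on the same side of both of the other, the 5 smallest p-values in each direction, and in each list the called members with the smallest p, at most 4, or up to 2 members as values where none was called. Some genes that the rule takes are not reported here. In the ranking by fold change 1 predicted gene model was passed over among the higher genes. Genes and lists named outside the rule stand in the closing section, and Gins2, Lcn2, Pdpn, Prox1 and Xist in the report, chosen after their values were seen.

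Gene coordinates, exons and GC content come from GENCODE M21 (GRCm38, the build that mm10 names), matched by gene name for 12188 tested genes, 96.3% of them. The GC correction, chosen after seeing the data, fits a loess curve (span 0.5) of each library's log2 deviation on transcript GC content, for genes above 2 on the log2 CPM scale, and enters it as an offset in the edgeR test. A variant of it used the GC content of the last 500 transcript bases. Alternatives written beforehand were DESeq2 size factors, upper-quartile scaling, library totals, the DESeq2 1.42 Wald test, edgeR's likelihood ratio and exact tests, limma-voom, no filter, a filter of 50 counts in 2 libraries, the replicate mark as a block, each library left out, a test against a 1.5-fold change, a minimum log2 fold change of 1, an adjusted p under 0.1, and removal of the cell-type marker genes.

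The tests were tried on simulated counts drawn for the 12656 genes of this comparison, with 200 genes changed. The fit recovered 50% of 1.5-fold and 76% of 2-fold changes with 12 false calls, 8.7% of its calls. With a GC trend added to the simulated Jun-cKO libraries it made 1302 false calls, 90.4% of its calls, and the GC-corrected fit made 3, recovering 37% and 71% of the changes. That trend was linear, the same in both Jun-cKO libraries and in the measure the correction uses, so success there was nearly assured. Real libraries also differed in GC trend within a group. With 5251 genes called in the data, the simulated shares of false calls do not carry over. The list test called the 1 shifted list and 0 of the other 38. Those lists were random and their genes were drawn independently. This therefore does not test lists with correlated members, such as the ribosomal list with an estimated correlation of 0.501. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. With 2 libraries per group, regrouping the libraries was not used as a test.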

Results

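RNA was profiled in lymphatic endothelial cells, the cells that line lymphatic vessels, sorted from mouse lungs at postnatal day 0 by absence of CD45, a leukocyte surface protein, and presence of CD31, an endothelial surface protein, and GFP. The animals carried a tamoxifen-dependent Cre recombinase under the Prox1 gene and a Rosa26 reporter that turns green after Cre acts. Jun-Ctrl animals had 1 floxed and 1 wild-type Jun allele, and Jun-cKO animals had both Jun alleles floxed. Each group had 2 libraries (n = 2 throughout), called replicate 1 and replicate 2 here, the second being the one whose title carries the word replicate. Total counts per library were 16037416 and 6483514 in Jun-Ctrl and 15558476 and 6911821 in Jun-cKO. A count was seen for 16297 and 15156 genes in the Jun-Ctrl libraries and for 14928 and 14186 genes in the Jun-cKO libraries. The design text has cells of a group mixed before amplification, so the p-values below measure only the spread between these libraries, which may be technical. The 2 libraries of a group differed by more than sampling noise, with a median chi-square per gene of 1.21 between the Jun-Ctrl and 1.48 between the Jun-cKO libraries against 0.455 from sampling alone. Separate amplification of 1 pool, or sequencing of 1 library in separate runs, could also give such a spread. The libraries are used as replicates because the labels list them as separate samples.

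The targeted gene was examined first, because it checks the labels. Jun, which encodes a subunit of the transcription factor AP-1, stood at 452 ± 27.7 CPM (counts scaled to library size; mean ± SD, n = 2) in Jun-Ctrl and at 499 ± 34.8 CPM (n = 2) in Jun-cKO. Its log2 fold change was 0.14 (SE 0.12, adjusted p = 0.354 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the 95% interval of the fold ran from 0.935 to 1.30. Jun did not fall in the libraries labelled Jun-cKO, so these are called Jun-cKO-labelled from here on, and every direction below rests on that label. The gene is a single-exon protein-coding gene on the minus strand of chromosome 4 (95049034 to 95052222, GRCm38). The sources used here do not say which part of it is floxed, and counts are per gene, so RNA from an altered allele would be counted wherever it matches. With a correction for GC content, chosen after seeing the data, the log2 fold change of Jun was 0.32 (adjusted p = 0.0208, against a range of 0.0208 to 0.813 over 17 alternatives).

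Of 18 tested AP-1 family genes, 2 rose and 3 fell in the Jun-cKO-labelled libraries, and the counts adjusted over the list alone were also 2 and 3. Atf3, a stress-induced partner of Jun, fell 2.65-fold from 225 ± 43.3 to 84.7 ± 0.337 CPM (adjusted p = 3.9e-13). Mafg fell 1.59-fold and Mafk 1.47-fold, and both encode small Maf proteins. Fosl2 rose 1.43-fold and Atf2 1.24-fold. Junb had a log2 fold change of 0.31 (SE 0.13, adjusted p = 0.0548), Jund of -0.20 (SE 0.12), Fos of 0.10 (SE 0.13) and Fosb of -0.13 (SE 0.12). Among the others, Maf was at 0.17, Maff at 0.07, Atf4 at 0.15, Atf7 at 0.23, Jdp2 at 0.03, Batf at -0.46 and Batf3 at 0.37 on the log2 scale, all without a call. As a set the family did not pass the camera test (adjusted p = 0.934), with a median log2 fold change of 0.09 and a mean of -0.08. The Atf2 and Mafk calls ended in DESeq2 (adjusted p = 0.063 and 0.11) and in the GC-corrected fit (0.637 and 0.133), and those of Mafg and Fosl2 without Jun-Ctrl replicate 1 (0.0589 and 0.0992). The Atf2 call also ended with upper-quartile scaling, with library totals and with the filter of 50 counts (adjusted p = 0.054, 0.0761 and 0.0539). Without Jun-Ctrl replicate 1 or 2 the adjusted p was 0.166 or 0.158 for Atf2 and 0.111 or 0.0673 for Mafk, without Jun-cKO-labelled replicate 2 it was 0.0739 for Atf2, and without Jun-cKO-labelled replicate 1 it was 0.136 for Mafk. Junb passed without Jun-cKO-labelled replicate 2 (log2 fold change 0.53, adjusted p = 0.000622) and after GC correction (0.70, adjusted p = 2.82e-05). Atf7 passed without Jun-cKO-labelled replicate 2 (adjusted p = 0.0301) and Maff after GC correction (0.00615).

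**Figure D1:**
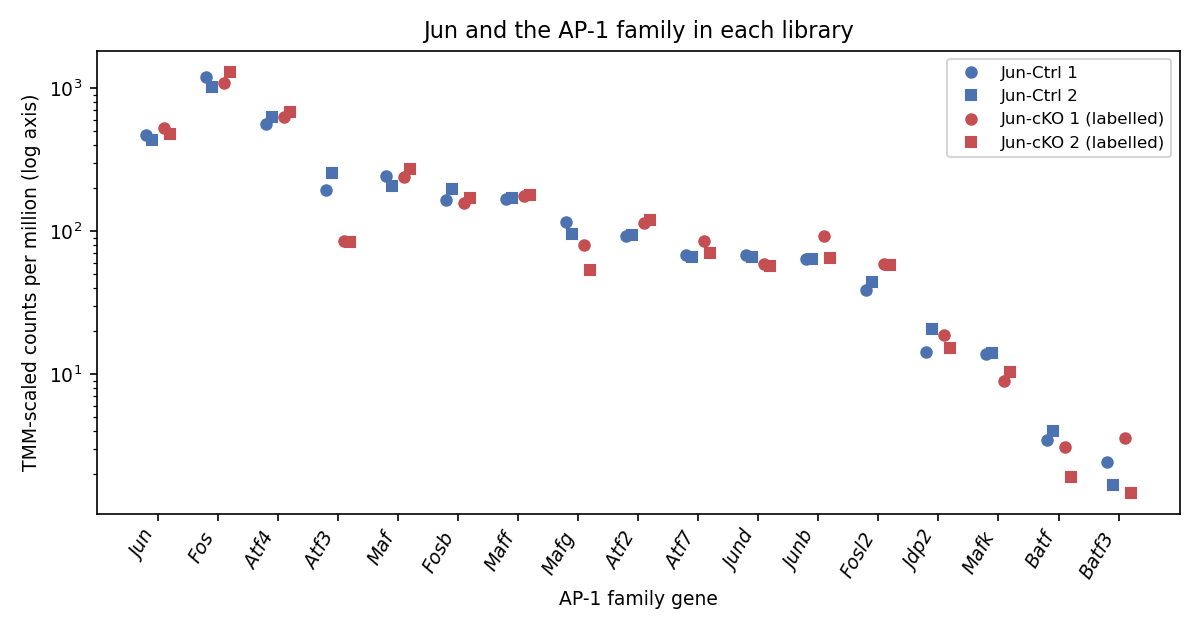
CPM (vertical log axis, TMM-scaled) of Jun and other tested AP-1 family genes in each library, with Jun-Ctrl in blue, Jun-cKO-labelled in red, circles for replicate 1 and squares for replicate 2. Jun lies at 452 CPM on average in Jun-Ctrl and 499 CPM in the Jun-cKO-labelled libraries, and Atf3 lies lower in both Jun-cKO-labelled libraries than in both Jun-Ctrl libraries.

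The comparison of the Jun-cKO-labelled with the Jun-Ctrl libraries asks which genes of lung lymphatic endothelial cells differ at birth when Cre can act on both Jun alleles in place of 1. Gzma, a granule protease of cytotoxic lymphocytes, had 0 counts in both Jun-Ctrl libraries and 22.0 ± 0.67 CPM in the Jun-cKO-labelled libraries, at least 167-fold higher against a floor of 3 counts over the group. Saa3, an acute phase protein, rose 61.8-fold from 0.686 ± 0.112 to 41.2 ± 1.89 CPM. In the other direction, the surfactant protein gene Sftpb fell 85.1-fold from 46.8 ± 0.946 to 0.393 ± 0.556 CPM, and the tight junction gene Cldn18 fell 74.0-fold. Sftpc, the surfactant protein of alveolar type 2 cells, fell 11.4-fold from 1300.0 ± 46.9 to 114 ± 2.32 CPM. Dlk1, a paternally expressed growth regulator, fell 12.7-fold.

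Of 12656 tested genes, 5251 passed an adjusted p of 0.05, of which 2408 were higher and 2843 lower in the Jun-cKO-labelled libraries. Calls with a log2 fold change of at least 1 in size were 310 higher and 1360 lower. The other genes with the highest fold changes by the fixed rule were the Y-linked Kdm5d and Ddx3y, AA467197, the glutamate receptor gene Gria2, the hypoxia-induced Ankrd37, the interferon-induced Rsad2, Trim34a and the kinase gene Pdk1, from 6.10-fold for Kdm5d to 3.30-fold for Pdk1. The other genes with the lowest fold changes were Mal2, Slc6a14, Myh14, Actg2, Atp6v0a4, Aqp5, Msln and Retnla, from 51.9-fold lower for Mal2 to 26.6-fold for Retnla. The smallest p-values among lower genes also included Lyz1 and Cxcl15, 15.5-fold and 11.6-fold lower, and among higher genes Serpina3n, 3.03-fold higher, and the predicted model Gm1821. Reads of Lyz1 and its near copy Lyz2, of Hspa1b and its near copy Hspa1a, and of Gm1821 are uncertain. The counting could split reads shared by copies, or drop them. Ccl21a of the lymphatic identity list had 0 counts in every library and was not tested. The total was 2992 without Jun-Ctrl replicate 1 and 3425 without Jun-Ctrl replicate 2, and DESeq2 called 3591 genes.

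Fold changes varied with expression level and base composition. Among genes with a mean under 4 CPM, 181 calls of at least 2-fold were higher and 739 lower. They were 72 and 376 from 4 to 16 CPM, 30 and 182 from 16 to 64 CPM, 24 and 54 in the next class and 3 and 9 in the class of highest expression. The median log2 fold change was -0.39 in the weakest class and 0.15 in the strongest. With at least 10 counts over one group and 0 in both libraries of the other, 244 genes were seen only in Jun-Ctrl and 29 only in the Jun-cKO-labelled libraries. Across genes, the log2 fold change fell with GC content (Spearman's rho = -0.336 over 12188 genes, which are not independent replicates). Between replicates 1 and 2 of a group the log2 ratio also varied with GC content, at rho = -0.275 in Jun-Ctrl and 0.215 in the Jun-cKO-labelled libraries. For single libraries, Jun-Ctrl over Jun-cKO-labelled, rho ran from 0.249 to 0.395, so a GC trend is not particular to the group comparison. The decile of genes with the lowest GC content held 400 higher and 119 lower calls, and the decile with the highest held 103 and 580. After GC correction 4710 genes were called, 1973 higher and 2737 lower, and 3809 of the 5251 calls were shared in the same direction.

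**Figure D2:**
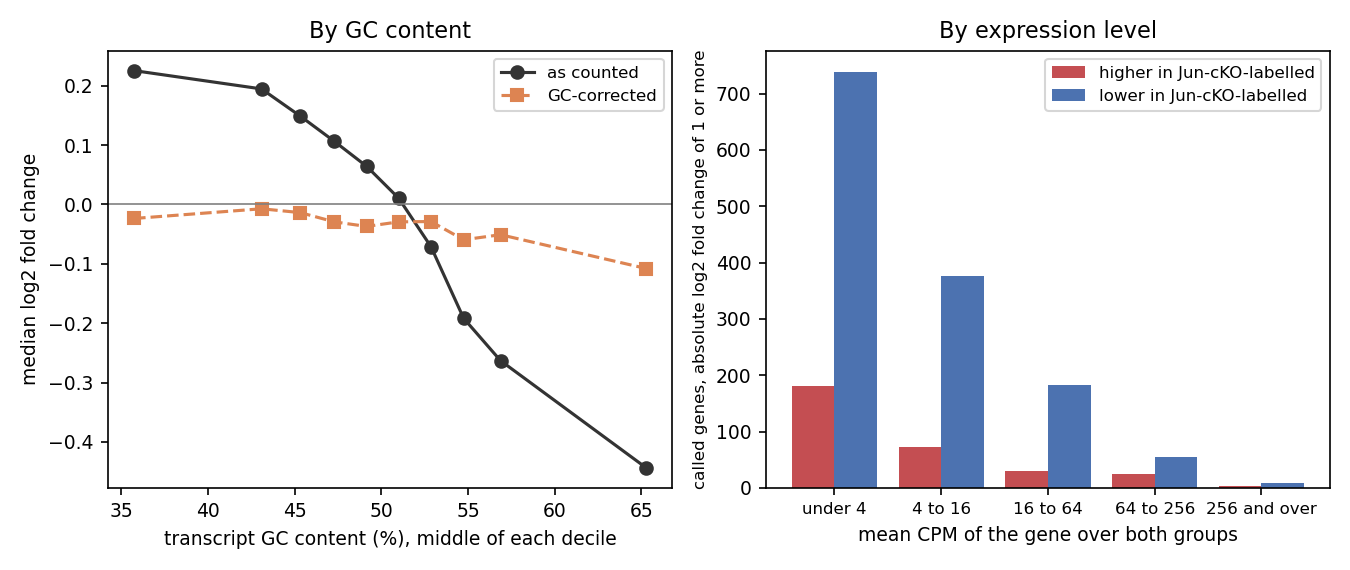
Left, the median log2 fold change (Jun-cKO-labelled minus Jun-Ctrl) in each decile of genes by transcript GC content in percent, as counted (black circles) and after GC correction (orange squares). Right, the number of called genes with an absolute log2 fold change of at least 1, higher (red) or lower (blue) in the Jun-cKO-labelled libraries, by the gene's mean CPM, where lower calls outnumber higher ones in each class, at 739 against 181 under 4 CPM and 182 against 30 from 16 to 64 CPM.

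Of 39 gene lists fixed before the data were examined, 35 had at least 5 tested members, and 8 of these passed the camera test, 2 higher and 6 lower. None of the 8 passed with an estimated correlation, where the smallest adjusted p was 0.36, and the fry test called 7 of them. Camera with an estimated correlation rests on the few residual degrees of freedom of 4 libraries, so hardly any list could pass it. The AP-1 target list, whose estimated correlation of -0.045 lay below the preset 0.01, still went from a camera p of 1.11e-08 to 0.025. These failures alone therefore do not show that correlation among genes accounts for the list results. The hypoxia and glycolysis list had the highest estimated correlation of the 8, 0.304 against the preset 0.01, and fry did not call it (adjusted p = 0.126). For that list, correlation among genes may account for the camera call.

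The marker lists of lung epithelial, immune, mesenchymal and mesothelial cells fell in the Jun-cKO-labelled libraries, and those of blood endothelial cells and cardiomyocytes did not pass. Of 23 lung epithelial markers, 20 fell and 1 rose (20 and 1 adjusted over the list alone), with a median log2 fold change of -2.80 (camera adjusted p = 2.24e-34, and adjusted p = 0.36 with an estimated correlation). Sftpa1 fell 9.59-fold from 83.4 ± 8.04 to 8.75 ± 0.147 CPM. The podoplanin gene Pdpn, which lymphatic cells also express, is on this list and had a log2 fold change of 0.15. Lcn2, the member that rose, was also the most abundant, and the summed CPM of the list was 3868 and 4160 in Jun-Ctrl and 3947 and 3566 in the Jun-cKO-labelled libraries. Of 16 tested immune markers, 13 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -1.18 (adjusted p = 2.59e-06, and adjusted p = 0.36 with an estimated correlation). The neutrophil gene S100a9 fell 2.75-fold from 216 ± 12.1 to 78.1 ± 11.7 CPM, the macrophage gene Cd68 fell 2.18-fold, Lyz2 3.12-fold and the monocyte gene Ly6c2 3.97-fold.

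Of 22 tested mesenchymal markers, 11 fell and 2 rose (11 and 2 adjusted over the list alone), with a median of -0.61 (adjusted p = 0.000588, and adjusted p = 0.361 with an estimated correlation). The collagen genes Col1a1 and Col1a2 fell 6.82-fold and 3.25-fold, and the smooth muscle genes Acta2 and Tagln fell 5.19-fold and 4.46-fold. Of 5 tested mesothelial markers, 2 fell and 1 rose (2 and 1 adjusted over the list alone), with a median of -0.46 (adjusted p = 0.00974, and adjusted p = 0.496 with an estimated correlation). Msln fell 27.9-fold and Krt19, which is also on the epithelial list, fell 16.4-fold, while Gpm6a, the most abundant of the 5, rose 1.47-fold, and the summed CPM of the list was 288 and 265 in Jun-Ctrl and 318 and 336 in the Jun-cKO-labelled libraries. The blood endothelial list went both ways, with 8 of 22 tested members higher and 8 lower, the same counts adjusted over the list alone. Its camera adjusted p was 0.656, with a median log2 fold change of -0.12 and a mean of -0.63, so the falls were larger. On it Hey1 rose 2.15-fold and Cxcl12 fell 7.88-fold. Plvap, a protein of fenestrated endothelium, fell 2.07-fold from 331 ± 7.12 to 158 ± 34.5 CPM.

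Markers of blood cells, heart and nerve were few. Among 4 tested platelet genes, Gp1bb fell 3.85-fold and Pf4 2.09-fold (2 lower, and 2 adjusted over the list alone), and the Pf4 call ended in DESeq2 and limma-voom (adjusted p = 0.187 and 0.0932), without Jun-Ctrl replicate 2 (0.543) and without Jun-cKO-labelled replicate 1 (0.322). Among 6 tested cardiomyocyte genes, Tnnt2 fell 5.34-fold and Myh7 5.00-fold (2 lower, and 2 adjusted over the list alone), with a list median of 0.09, a mean of -0.51 and an adjusted p of 0.809. Myh7 lost its call in DESeq2 (adjusted p = 0.118), without Jun-Ctrl replicate 1 or 2 (0.0649 or 0.132) and without Jun-cKO-labelled replicate 1 (0.391). The erythroid gene Fech did not pass, at a log2 fold change of 0.31 (SE 0.13, adjusted p = 0.0524), and the 3 tested erythroid genes gave 0 calls, as they did adjusted over the list alone. Fech passed without Jun-cKO-labelled replicate 2 (adjusted p = 0.0396). Of 2 tested neural genes, Uchl1 fell 1.38-fold (1 lower, also adjusted over the list alone), a call that ended in DESeq2 (adjusted p = 0.104), after GC correction (0.262), without Jun-Ctrl replicate 1 or 2 (0.132 or 0.0738) and without Jun-cKO-labelled replicate 1 (0.192). Mitochondrially encoded genes were not analysed here, with 0 of the 15 listed genes tested.

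Transcripts of the Y chromosome rose. Ddx3y rose 3.76-fold (log2 fold change 1.91, SE 0.13), Eif2s3y 3.10-fold, Kdm5d 6.10-fold and Uty 2.40-fold, and 1 member of the list, Xist of the inactive X chromosome, fell, with a log2 fold change of -0.41 (SE 0.13). That made 4 higher and 1 lower of 5 tested, the same adjusted over the list alone (camera adjusted p = 4.44e-05, and adjusted p = 0.361 with an estimated correlation). The labels do not give the sex of the pooled mice, and Uty lost its call without Jun-Ctrl replicate 1 (adjusted p = 0.107).

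**Figure D3:**
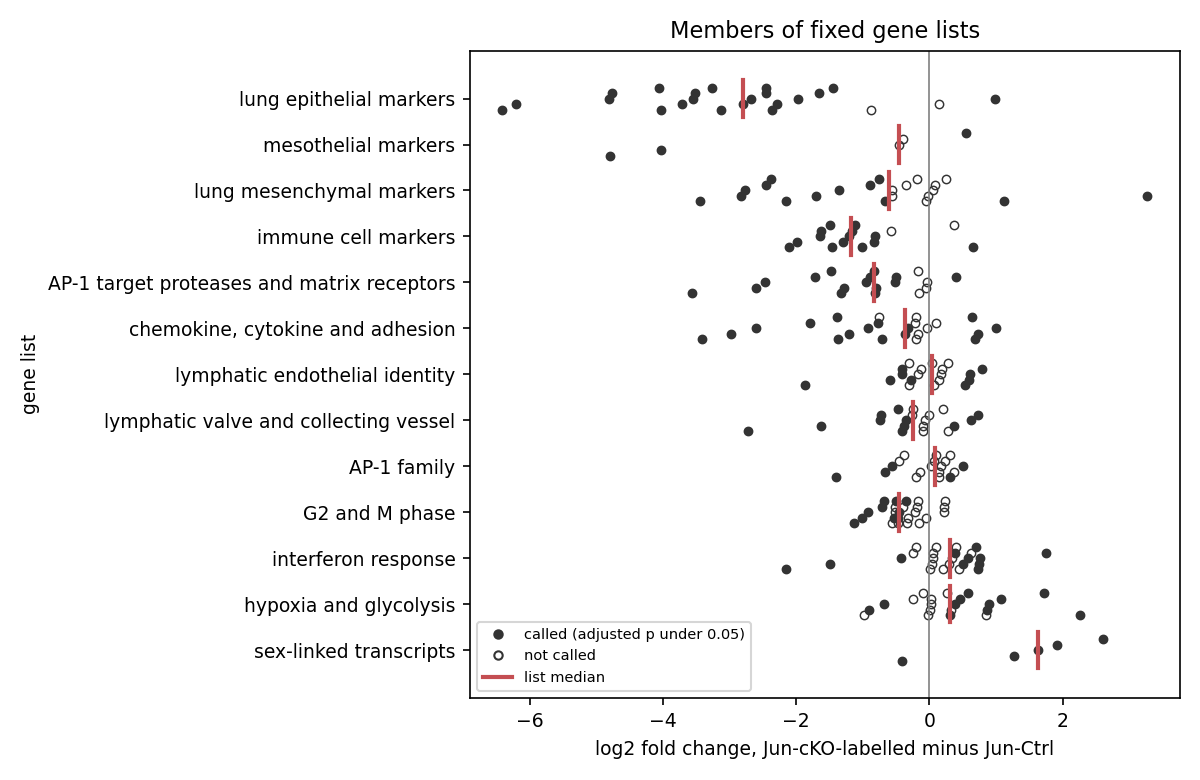
Log2 fold change (Jun-cKO-labelled minus Jun-Ctrl, horizontal axis) of each tested member of 13 of the fixed gene lists, with filled circles for called genes, open circles for genes not called and red bars for list medians. Epithelial markers have a median of -2.80, the AP-1 target list of -0.83 and the hypoxia list of 0.31.

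Proteases, matrix receptors and other genes known as AP-1 targets fell together. Hmox1, the haem-degrading enzyme, fell 6.09-fold (log2 fold change -2.61, SE 0.13, adjusted p = 5.21e-22), the fibronectin receptor subunit Itga5 2.80-fold, the hyaluronan receptor Cd44 3.30-fold and the growth factor gene Hbegf 2.52-fold. Of 19 tested members 14 fell and 1 rose, the same adjusted over the list alone, with a median log2 fold change of -0.83 (camera adjusted p = 1.93e-07, and adjusted p = 0.36 with an estimated correlation). The median was -0.78 after GC correction. Several of these genes are also expressed by epithelial, mesenchymal or immune cells, whose marker lists had medians of -2.80, -0.61 and -1.18 in the same comparison. Of 26 immediate early and dissociation response genes, which AP-1 and tissue digestion both engage, 11 fell and 2 rose (11 and 3 adjusted over the list alone). Nr4a1 fell 2.62-fold, Nr4a2 2.50-fold and Socs3 1.81-fold, and the list had an adjusted p of 0.0725, which became 0.0333 without Jun-Ctrl replicate 2 and 0.042 without Jun-cKO-labelled replicate 1. With an estimated correlation its adjusted p = 0.52, and after GC correction it was 0.573, with 6 higher and 8 lower of 25 genes and a median of -0.06 against -0.20 as counted. It passed with the GC correction on the last 500 bases (0.0214), by fry (0.0312) and with the filter of 50 counts (0.0333).

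Chemokines, cytokines and adhesion genes fell as a list. Cxcl12, a chemokine for leukocytes and progenitors, fell 7.88-fold (log2 fold change -2.98, SE 0.24), and the monocyte chemokines Ccl7 and Ccl2 fell 2.61-fold and 1.90-fold. Ackr2, a scavenging chemokine receptor of lymphatic endothelium, rose 1.66-fold from 75.5 ± 0.485 to 125 ± 6.31 CPM. Of 23 tested members 12 fell and 4 rose, the same adjusted over the list alone, with a median of -0.37 (adjusted p = 0.0207, and adjusted p = 0.52 with an estimated correlation). The list was at an adjusted p of 0.0689 without Jun-Ctrl replicate 1, and the immune markers that fell beside it had a median of -1.18. Among interferon response genes 8 of 24 rose and 3 fell (8 and 3 adjusted over the list alone), with a median of 0.32 and an adjusted p of 0.0725, or 0.0495 without Jun-Ctrl replicate 2, 0.0548 after GC correction, 0.0304 with that on the last 500 bases and adjusted p = 0.52 with an estimated correlation. There Rsad2 rose 3.37-fold, Ifit1 1.68-fold, Ifi44 1.67-fold and Psmb8 1.69-fold. In antigen presentation 3 of 10 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.205, 0.0327 after GC correction on whole transcripts but no call with that on the last 500 bases, and adjusted p = 0.532 with an estimated correlation), and of these Psmb8 kept its call in each alternative, while Nlrc5 (3.41-fold), H2-Ab1 (1.91-fold) and Tapbp (1.30-fold lower) lost theirs in DESeq2 (adjusted p = 0.0534, 0.183 and 0.096). Tapbp also lost its call with both GC corrections, at log2 fold changes of -0.13 (adjusted p = 0.465) and -0.30 (0.0654) against -0.38 as counted. Without Jun-Ctrl replicate 1 or 2 the adjusted p was 0.0877 or 0.0579 for Nlrc5, 0.166 or 0.117 for H2-Ab1 and 0.118 or 0.102 for Tapbp. It was 0.184 for H2-Ab1 without Jun-cKO-labelled replicate 1, and 0.0599 for Nlrc5 and 0.278 for Tapbp without Jun-cKO-labelled replicate 2.

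Hypoxia and glycolysis genes rose as a list by camera with the preset correlation. Ankrd37 rose 4.77-fold from 5.81 ± 1.30 to 29.2 ± 2.75 CPM, Pdk1, a kinase that inhibits pyruvate dehydrogenase, 3.30-fold, the glycolytic regulator Pfkfb3 1.82-fold and the glycolytic enzyme gene Pgk1 1.86-fold. Of 21 tested members 9 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.31 (adjusted p = 0.0195, and adjusted p = 0.614 with an estimated correlation). The list was at an adjusted p of 0.202 without Jun-Ctrl replicate 1, and the fry test gave 0.126. The Pgk1 call ended in DESeq2 (adjusted p = 0.0882).

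Genes of lymphatic identity moved in both directions. Lyve1, a hyaluronan receptor of lymphatic vessels, rose 1.53-fold from 6186 ± 304 to 9450 ± 1145 CPM, and the secreted glycoprotein gene Reln rose 1.72-fold from 1618 ± 79.6 to 2787 ± 423 CPM. Flt4, the receptor for VEGF-C, fell 1.51-fold from 1588 ± 126 to 1049 ± 215 CPM, and the ferroxidase gene Cp rose 1.51-fold. Prox1, whose gene drives the Cre, had a log2 fold change of -0.31 (SE 0.14, adjusted p = 0.0686), and of -0.48 after GC correction (adjusted p = 0.00404). Of 19 tested members 4 rose and 5 fell (5 and 5 adjusted over the list alone), with a median of 0.04, a mean of -0.06 and an adjusted p of 0.71. Among valve and collecting vessel genes 3 of 19 rose and 8 fell (3 and 9 adjusted over the list alone; adjusted p = 0.112). The list's median was -0.25 as counted and -0.01 after GC correction (adjusted p = 0.811), while it passed with that on the last 500 bases (0.0426) and by fry (0.0455), and had an adjusted p = 0.52 with an estimated correlation. Foxc2, a transcription factor of lymphatic valves, rose 1.66-fold from 144 ± 15.8 to 241 ± 11.9 CPM, while the mechanosensitive channel gene Piezo1 fell 6.61-fold, the laminin gene Lama5 3.09-fold and Neo1 1.67-fold. A contribution of RNA from epithelial, mesenchymal or immune cells to these falls was not tested.

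In VEGF, angiopoietin and adrenomedullin signalling 4 of 20 rose and 7 fell, or 5 and 7 adjusted over the list alone. The camera adjusted p was 0.585, while fry called the list lower (0.012). Nrp1, a co-receptor for VEGF and semaphorins, fell 7.53-fold from 52.7 ± 1.43 to 6.88 ± 0.747 CPM, and Vegfb fell 1.58-fold, a call that ended after GC correction (adjusted p = 0.0637). Whether RNA of epithelial, mesenchymal or immune cells, whose marker lists fell, contributes to the fall of Nrp1 was not tested. Angpt2 rose 1.65-fold and the adrenomedullin receptor gene Calcrl 1.54-fold. Among junction genes 5 of 18 rose and 6 fell (7 and 6 adjusted over the list alone), with a median of 0.24 and a mean of -0.24. The camera adjusted p was 0.938, while fry called the list lower (0.0305). The plakoglobin gene Jup fell 2.68-fold and Cgn 4.86-fold, both also expressed in epithelium, whose markers had a median of -2.80, and Jam3 rose 1.51-fold. Of 26 guidance genes 4 rose and 13 fell, or 4 and 15 adjusted over the list alone (camera adjusted p = 0.0893, and 0.012 by fry, lower). Sema3e and Sema4a had 0 counts in both Jun-cKO-labelled libraries and were at least 27.4-fold and 12.4-fold lower by the same floor, Sema7a fell 3.74-fold, and Ephb4 fell 1.66-fold from 109 ± 2.21 to 65.3 ± 5.31 CPM.

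Among signalling lists none passed. In the TGF-beta and BMP pathway 5 of 21 rose and 7 fell (6 and 7 adjusted over the list alone), with a median of 0.01, a mean of -0.23 and an adjusted p of 0.88. Id1, a BMP target, rose 2.28-fold from 69.1 ± 1.62 to 158 ± 5.24 CPM and the co-receptor gene Tgfbr3 rose 2.25-fold, while the ligand gene Tgfb1 fell 4.49-fold. In the Notch pathway 2 of 14 rose and 3 fell, the same adjusted over the list alone, and the test's sign was up while the median was -0.19 and the mean -0.09 (adjusted p = 0.988). The targets Hey1 and Nrarp rose 2.15-fold and 1.54-fold, and the receptors Notch2 and Notch1 fell 1.65-fold and 1.39-fold, the Notch1 call ending after GC correction (adjusted p = 0.102). In the Wnt pathway 3 of 16 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.356), with Tcf7l1, Lrp5 and Lef1 lower by 1.64-, 2.02- and 4.36-fold and Nkd1 at a log2 fold change of -0.68. Among YAP and TAZ targets 2 of 16 rose and 7 fell (3 and 7 adjusted over the list alone; adjusted p = 0.11, or 0.0435 without Jun-Ctrl replicate 2), with Myof 6.83-fold, F3 5.08-fold, Amotl1 1.78-fold and Cyr61 1.61-fold lower. The list's median was -0.22 as counted and 0.05 over 14 genes after GC correction, where the test's sign stayed down (adjusted p = 0.518), and the list had an adjusted p = 0.52 with an estimated correlation.

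No cell cycle gene on the phase lists rose as counted, and 1 S phase gene, Gins2, rose after GC correction (log2 fold change 0.55, adjusted p = 0.0413). Of 25 genes of G2 and M phase 10 fell, and 10 adjusted over the list alone, with a median of -0.45 and an adjusted p of 0.0636 that became 0.0075 after GC correction, 0.0297 without Jun-Ctrl replicate 2 and 0.0356 without Jun-cKO-labelled replicate 2. It was at adjusted p = 0.614 with an estimated correlation, and the epithelial, mesenchymal and immune markers that fell beside it had medians of -2.80, -0.61 and -1.18. The mitotic kinase genes Plk1 and Aurkb fell 2.19-fold and 1.90-fold, and Nusap1 and Cenpe fell 2.02-fold and 1.61-fold, Aurkb and Cenpe losing their calls without Jun-Ctrl replicate 1 (adjusted p = 0.0771 and 0.0582) and Cenpe also without Jun-cKO-labelled replicate 1 (0.105). Of 25 S phase genes 6 fell, and 5 adjusted over the list alone (adjusted p = 0.67), among them E2f1 (2.26-fold), Cdc6 (2.39-fold) and Mcm7 (1.55-fold), the last not called without Jun-Ctrl replicate 1 (adjusted p = 0.0549). Among D cyclins and cell cycle inhibitors 1 of 14 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.11). The fry test called this list and the S phase list lower (adjusted p = 0.0115 and 0.0455). Ccnd2 fell 2.58-fold from 289 ± 13.1 to 112 ± 1.03 CPM, the inhibitor gene Cdkn1a 1.91-fold from 371 ± 27.0 to 193 ± 16.4 CPM and Cdkn2b 3.76-fold, the last without a call when Jun-Ctrl replicate 1 was left out (adjusted p = 0.112), and Cdk2 rose, with a log2 fold change of 0.58. Among p53 targets 3 of 21 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.67), with Eda2r 3.21-fold higher, Perp 4.13-fold lower and Gtse1 2.40-fold lower, Gtse1 losing its call without Jun-Ctrl replicate 1 (adjusted p = 0.0549). Among apoptosis regulators 7 of 26 rose and 5 fell, the same adjusted over the list alone, with a median of -0.02, a mean of 0.02 and an adjusted p of 0.498. Tnfrsf1a, Apaf1 and Casp8 rose 1.93-, 1.72- and 1.52-fold.

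Of the other metabolic and stress lists none passed the camera test. The fry test called cholesterol synthesis (adjusted p = 0.00831) and the unfolded protein and integrated stress response (0.00706), both lower. Cholesterol synthesis had 8 of 19 genes lower and 0 higher, the same adjusted over the list alone (median -0.28, adjusted p = 0.0636, 0.037 after GC correction, and adjusted p = 0.52 with an estimated correlation), with Lss 3.72-fold, Mvk 2.36-fold, Mvd 1.73-fold and Insig1 1.42-fold lower. The list was at 0.0449 without Jun-Ctrl replicate 2. The Mvd call ended after GC correction (adjusted p = 0.0655), and the Insig1 call without Jun-Ctrl replicate 1 (0.0983) and without Jun-cKO-labelled replicate 2 (0.0641). Oxidative phosphorylation had 8 of 26 higher and 0 lower, the same adjusted over the list alone (median 0.13, adjusted p = 0.0725, 0.037 after GC correction, and adjusted p = 0.614 with an estimated correlation), with Uqcrc1 1.58-fold, Cox5b 1.36-fold, Cox6a1 1.34-fold and Cox5a 1.32-fold higher, while the list was at 0.0297 without Jun-Ctrl replicate 2. Cox5b and Cox6a1 lost their calls without Jun-Ctrl replicate 1 (adjusted p = 0.0943 and 0.21) and Cox5a without Jun-Ctrl replicate 2 (0.129). Cytosolic ribosomal proteins had 7 of 35 higher and 0 lower, the same adjusted over the list alone (median 0.12, adjusted p = 0.0725, 0.0144 after GC correction, and adjusted p = 0.79 with an estimated correlation), with Rps2 1.56-fold, Rpl3 1.54-fold, Rpl23 1.40-fold and Rps6 1.32-fold higher. That list was at 0.00102 without Jun-Ctrl replicate 2 and 0.00554 without Jun-cKO-labelled replicate 1, and the fry test gave 0.515. Without Jun-Ctrl replicate 1 the adjusted p was 0.0695 for Rps2, 0.086 for Rpl3 and 0.0876 for Rps6, without Jun-Ctrl replicate 2 it was 0.058 for Rpl23 and 0.138 for Rps6, and without Jun-cKO-labelled replicate 2 it was 0.102 for Rps6. Rpl3 also lost its call in DESeq2 (0.0729), and ribosomal protein genes have many processed copies that can share reads.

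In fatty acid uptake and oxidation 7 of 20 rose and 3 fell (8 and 3 adjusted over the list alone; adjusted p = 0.356). Lpl, which releases fatty acids from lipoproteins, rose 1.61-fold from 267 ± 15.6 to 429 ± 38.1 CPM, while the coactivator gene Ppargc1a fell 3.16-fold, Fabp5 1.73-fold and Hadha 1.73-fold. In the unfolded protein and integrated stress response 4 of 24 rose and 8 fell, the same adjusted over the list alone (camera adjusted p = 0.67, but 0.00706 by fry, towards lower). Atf5 fell 2.55-fold, Phgdh 4.15-fold and Ppp1r15a 1.67-fold, and Xbp1 rose 1.49-fold, a call that ended without Jun-Ctrl replicate 2 (adjusted p = 0.0826). Of 14 heat shock genes 3 rose and 3 fell, the same adjusted over the list alone, and the test's sign was up with a median of -0.04 and a mean of -0.06 (adjusted p = 0.876). Hsph1 rose 1.49-fold and Hspa1b rose, with a log2 fold change of 1.43, Cryab fell 5.78-fold and Hspa8 1.39-fold, the Hspa8 call ending without Jun-Ctrl replicate 2 (adjusted p = 0.142).

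Among genes of the extracellular matrix and basement membrane 4 of 28 rose and 10 fell, or 5 and 10 adjusted over the list alone. The camera adjusted p was 0.203, and fry called the list lower (0.0239). The collagen VI genes Col6a1 and Col6a2 fell 7.21-fold and 10.7-fold, from 24.0 ± 3.26 to 3.30 ± 0.131 CPM for Col6a1, beside the mesenchymal markers with their median of -0.61. Postn, a matricellular protein, rose 2.18-fold from 164 ± 26.4 to 359 ± 44.3 CPM.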

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

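The corrections for GC content were chosen after seeing the data, and the other settings before. The 3 other scalings, the other edgeR tests, limma-voom, both filters, an adjusted p under 0.1 and both GC corrections kept the 3 counts of called genes within 1.5 times, and no named gene turned its direction while called. DESeq2 called 1564 genes higher. A test against a 1.5-fold change called 1453 genes (261 higher, 1192 lower), and a minimum log2 fold change of 1 left 1670 (310 higher, 1360 lower), where the stricter criterion itself lowers the count. Leaving out 1 library gave 2992 to 4794 called genes, 1177 to 2214 higher and 1815 to 2656 lower, with the fewest without Jun-Ctrl replicate 1. There the lone library of a group is assumed to vary like the other group. Jun stayed between 0.06 and 0.22 on the log2 scale in these fits without a call, and passed only with the correction on whole-transcript GC content, at 0.32. It was 0.04 with that on the last 500 bases. The cause of the difference was not tested.

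The 8 called lists became 0 with an estimated correlation, 17 with fry, 4 without the cell-type marker genes, where the marker lists themselves drop out, 13 with the GC correction, 15 with that on the last 500 bases, and 5 to 15 with 1 library left out. Apart from these marker lists and the few degrees of freedom behind the estimated correlation, the causes were not tested. The replicate block, the titles' only shared mark, gave 5426 called genes (2521 higher, 2905 lower) and 8 lists, and changed no call of a named gene except Junb and Fech, which passed. The deviations of the libraries sharing the mark correlated at 0.073, too few pairs to show a pairing. Of the named genes, 144 kept their side of the threshold without Jun-Ctrl replicate 1, 153 without Jun-Ctrl replicate 2, 160 and 158 without the Jun-cKO-labelled replicates 1 and 2, 156 in DESeq2 and 155 with the GC correction. Weak genes varied most between libraries: under 4 on the log2 CPM scale the SD between the Jun-cKO-labelled libraries was 0.379 or more, against 0.191 above 8. Depth and amplification noise were not told apart. The prior-count setting was not run, since it was meant for 1 library per group, nor was a crossed block.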

Other observations

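The gene lists of this part, the genes named from them and all tests except that of the pan-epithelial genes were chosen after the results were seen.

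Of 24 tested acute phase and complement genes 13 rose and 3 fell in the Jun-cKO-labelled libraries by edgeR. The list was put together after Saa3 and Serpina3n had been seen among the higher genes and holds both, so no list test is given for it. Beside Saa3, Serpina3n rose 3.03-fold from 83.7 ± 1.72 to 253 ± 36.0 CPM (n = 2 per group), and the log2 fold changes were 1.35 (SE 0.18) for complement factor B, Cfb, 1.28 (SE 0.13) for the C1 inhibitor gene Serping1, 1.32 (SE 0.12) for the oncostatin M receptor gene Osmr and 0.99 (SE 0.13) for Lcn2. The interleukin 6 receptor gene Il6ra fell, at -2.30 (SE 0.22), and C3 was at -0.26 (SE 0.18). The median was 0.43, and 0.28 after GC correction.

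Imprinted growth genes split. H19 fell from 17911 ± 20.4 to 4286 ± 782 CPM, Igf2 from 18687 ± 335 to 10209 ± 987 CPM, Meg3 from 192 ± 15.2 to 39.1 ± 4.17 CPM and Dlk1 12.7-fold, while Gnas rose from 6733 ± 251 to 10573 ± 420 CPM, Grb10 from 433 ± 20.7 to 632 ± 8.11 CPM and Plagl1 from 49.3 ± 14.1 to 94.6 ± 0.298 CPM. Of 17 tested genes 6 rose and 6 fell, with a median log2 fold change of 0.19, a mean of -0.61 and a median of 0.04 after GC correction. This list was chosen after Dlk1 had been seen, and no list test is given for it. H19, Igf2, Dlk1 and Meg3 are abundant in fetal mesenchyme, whose markers had a median of -0.61. The tested mesenchymal markers together reached 1718 and 1619 CPM in Jun-Ctrl and 1545 and 1549 CPM in the Jun-cKO-labelled libraries. Their sum holds Postn, which rose from 164 to 359 CPM, while Col1a1 fell 6.82-fold, with 11 of 22 markers lower and 2 higher. The sum therefore does not measure mesenchymal RNA and cannot decide whether such RNA is the source of the H19 and Igf2 falls. Whether such RNA contributes to the falls of Dlk1 and Meg3 was not tested. Of 294 tested zinc finger genes named Zfp, 91 rose and 28 fell, with a median of 0.28 that was 0.15 after GC correction. Their median GC content was 45.6%.

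Jun was not lower in the Jun-cKO-labelled libraries. As the whole source of the Jun reads, RNA of epithelial, mesenchymal or immune cells is argued against by 9 of their abundant transcripts, among them Sftpc, Col1a2 and S100a9, which together reached 357 CPM there and 2033 CPM in Jun-Ctrl, while Jun stood at 499 CPM. Exchanged group labels and reads outside the deleted part cannot be told apart from an allele that still yields RNA: the upper bound of the Jun log2 fold change was 0.38, the annotation gives Jun 1 exon, and the sources used here do not say which part is floxed. RNA of blood endothelial cells, which the sort on CD31 keeps but that on GFP from a Prox1-driven Cre should remove, or cells in which Cre did not act on both alleles, may also supply Jun reads, and neither was tested. No biological explanation, such as a rise of Jun RNA from the remaining sequence, was tested.

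Epithelial markers fell further than mesenchymal ones. The epithelial median lay below the mesenchymal one by a difference of -2.19 on the log2 scale (permutation of genes, p = 0.00023, 100000 resamples, two-sided). That p treats genes as independent and measures no spread between libraries. An equal dilution by every other cell type would lower alike only markers absent from the sorted cells. The mesenchymal list held Col1a1, 6.82-fold lower, and Postn, up from 164 to 359 CPM, with 11 of 22 lower and 2 higher. The difference therefore cannot decide on such a dilution. GC content as the source of the epithelial fall is argued against by a median that stayed at -2.81 after correction. More epithelial cells or epithelial RNA in the Jun-Ctrl pool may account for it: 22 pan-epithelial genes outside the fixed lists had a median of -1.91, with 14 lower and 2 higher (camera adjusted p = 0.202 with an estimated correlation), although Cd24a, the most abundant of them, rose, so that their summed CPM went from 555 and 538 to 861 and 803, and although a sort on CD31 and GFP should remove such cells (of the 23 markers, Pdpn at 649 and Lcn2 at 1422 CPM in Jun-Ctrl are also high in these sorted cells). The surfactant marker Sftpc stood at 1300.0 CPM in Jun-Ctrl. An effect of the Jun genotype on epithelial genes in sorted cells stays open, as do pools that differ in sex, since Y-linked transcripts rose.

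Large changes were mostly lower. Base composition as the whole source is argued against by the GC-corrected fit, where 80.3% of the calls with a log2 fold change of at least 1 in size were lower, against 81.5% of them in the same genes as counted. Fewer distinct RNA molecules in the Jun-cKO-labelled amplification would lose weak transcripts at random and keep their sum, and is argued against as the whole source by genes outside the lists of other cells chosen for under 4 CPM in 1 Jun-Ctrl library, whose summed CPM in the Jun-cKO-labelled libraries was 0.85 (95% bootstrap interval over genes 0.822 to 0.879) or 0.881 (0.855 to 0.909) of that in the other Jun-Ctrl library. These intervals resample genes and measure no spread between libraries, and each ratio has 1 Jun-Ctrl library as its base. RNA of other cells in the Jun-Ctrl pool beyond the listed markers may contribute and was not tested further. A biological loss of weak transcripts with the Jun genotype stays open.

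A hypothesis that DNA carried along with the floxed allele changes many genes around Jun was not borne out. Within 10 Mb of Jun 18 of 46 tested genes were called, 39.1%, against 41.5% of the 12121 other placed genes (one-sided Fisher's exact p = 0.68). With so high a share called everywhere, the test cannot speak to a change of a few genes there. Jun-Ctrl animals also carried 1 floxed allele.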
